A study of Mus musculus with 4 samples.

How the data were processed

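Gene expression was measured in 4 pools of thymic epithelial cells (TECs) sorted from mice, each on 1 single-colour (Cy3) microarray. Per the labels' protocols, mice aged 3 weeks that carried the tamoxifen-inducible K14-CreERT2 recombinase received 1 mg of tamoxifen on each of 3 days, and CD45-negative EpCAM-positive cells were sorted 4 days later. The sort followed a magnetic depletion of CD45- and Ter119-bearing cells, and cDNA was amplified from 10 ng of RNA. Mice with both Meis1 alleles floxed (Meis1-CKO) were compared with mice with 1 floxed and 1 normal allele, which the labels call WT and which are called control here. Each genotype had 2 pools of 6 mice, from 2 independent experiments.

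The deposited scanner output holds linear spot intensity values. Per the file headers, these were background-subtracted and spatially detrended within each array by Agilent Feature Extraction 9.5.3.1, with no scaling between arrays, and low values were replaced by surrogates. The deposited value table holds log2 values whose processing is not given in the sources used here. Set against the scanner values over 20818 probes above background on all 4 arrays, differences between its columns had a slope of 1 and a correlation of 1 with differences of the log2 signals after scaling to each array's 75th percentile. Every row of it had a median of 0 over the 4 columns, so each probe had been centred. Its column medians were 0.04 and 0.09 for control 1 and 2 and -0.06 and -0.12 for Meis1-CKO 1 and 2. Its scale, centring and direction were thus settled from the values, and all 41174 probes of the arrays had a row in it.

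The log2 processed signal minus each array's 75th percentile over non-control spots was used. Of 45018 spots, 1639 control spots were left out, as were between 63 and 78 spots per array flagged as outliers, and the spots of 1 probe were averaged. A probe was tested where it was well above background on both arrays of at least 1 group (24266 probes), and the probe with the highest mean over the 4 arrays stood for its gene. This gave 16810 features, 14281 of them with a gene symbol. Gene symbols came from the array files and were updated by RefSeq accession for 26690 of the 41174 probes, and by a single matching older symbol for 945, through a RefSeq gene table of another genome assembly, GRCm38.p6, whose coordinates were not used. A total of 6840 probes had no symbol. Probe coordinates are those of the array files, on mm9.

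The groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on all 4 arrays, without a block, and p-values were adjusted by Benjamini-Hochberg over all features at a threshold of 0.05. With 2 residual degrees of freedom, 5.51 in all after moderation, the number of arrays limits the precision. A count of features with at least a 2-fold difference and both Meis1-CKO arrays beyond both control arrays (called separated) was kept beside the test. For a feature well above background on neither array of a group, the fold is a bound, computed against the higher of the dim signal and the lowest signal above background on each array, and is written as at least N-fold. Differences of a feature above background on 1 array of a group rest in part on a dim signal. The 44 gene lists, covering TEC subsets, signalling pathways and cell types that a sort could carry over, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 43 lists with at least 5 tested members, and with an estimated correlation and limma's fry beside it. The lists, the comparison and the alternatives were fixed before the data were examined.

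The genes named are Meis1, up to 12 in each direction, up to 4 members with the smallest p of a list, and 14 TEC genes named whatever their values. The 12 are those with a symbol that passed the test with separated arrays. Where too few passed, they are the largest differences among genes above background on all 4 arrays with separated arrays, at least a 2-fold difference and an unadjusted p under 0.05. Clone names were passed over, and the results of 3 genes that these rules name are not reported. Alpha-defensin genes and 4 further lists, of Paneth cell, intestinal, dendritic cell and leukocyte genes, were added after values had been seen.

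Per the file headers, control 1 and Meis1-CKO 1 were on 1 slide and scanned together (slide 1), and control 2 and Meis1-CKO 2 on another (slide 2). Slide, scan and replicate number therefore coincide, and differences are given within each slide as well. The deviations of same-numbered arrays from their group means had a correlation of 0.13 across genes. The labels do not tie a number to a shared day or litter, so the fit with the number as a block is an alternative.

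The test was checked on simulated data with the real means of 16802 features, their spreads as moderated by limma, and 200 changed genes. Moderated spreads vary less between genes than the observed ones, so the shares called may be too favourable. Of the 50 genes changed at each size, limma called 2% at 2-fold, 10% at 4-fold, 70% at 8-fold and 94% at 16-fold. It also called 5 features outside those genes, and 1275 unchanged features had separated arrays and at least a 2-fold difference. A simulated list of 30 genes shifted by 1 on the log2 scale had a camera p of 3.57e-14, and an unshifted one a p of 0.563. The simulated genes were drawn independently and the 4 arrays alike. The check therefore does not cover lists of correlated genes (estimated at 0.694 for the interferon list) or an array that stands apart.

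The alternatives were normexp background correction with an offset of 50 and quantile normalization, quantile normalization of the processed signal, median centring, the deposited value table, no filter on dim probes, features above background on all 4 arrays, all probes as separate features, the mean of a gene's probes, eBayes with a trend and robust moderation, the replicate block, a threshold of 0.1, and leaving out each array in turn. The exons that are floxed are not given in the sources used here.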

Results

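Expression in TECs 4 days after induced deletion of Meis1, a homeobox transcription factor, was compared with that in TECs of controls with 1 floxed and 1 normal allele. There were 2 control pools and 2 Meis1-CKO pools, each of 6 mice. Between 58.6% and 63.6% of probe spots were well above background on each array, no spot was saturated, and the 75th percentile of the signal was 93.2 and 137 in control 1 and 2 and 109 and 152 in Meis1-CKO 1 and 2. Across 16802 features, control 1 correlated at 0.936 with control 2 and at 0.940 with Meis1-CKO 1, and control 2 at 0.943 with Meis1-CKO 1. Meis1-CKO 2 stood apart from the rest, with correlations of 0.857 with control 1, 0.884 with control 2 and 0.865 with Meis1-CKO 1. Genes are not independent replicates, so these values only describe the arrays.

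Meis1 itself was measured by 2 probes on the minus strand of chromosome 11. The first (positions 18911247 to 18911306 on mm9, sequence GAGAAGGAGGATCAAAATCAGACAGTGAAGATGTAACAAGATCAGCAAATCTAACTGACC) read -0.12 and -0.91 in control 1 and 2 and -0.44 and -2.08 in Meis1-CKO 1 and 2, as log2 signal relative to the 75th percentile. Its log2 difference of Meis1-CKO minus control was -0.75 (SE 0.69, n = 2 pools each, limma adjusted p = 1), with -0.32 on slide 1 and -1.17 on slide 2. Without Meis1-CKO 2 the difference from the mean of both controls was 0.08, although Meis1-CKO 1 read below control 1 of its own slide. The sign thus depended on Meis1-CKO 2 only where the slides were not matched. The other probe (positions 18781206 to 18781265) was well above background on both control arrays and on neither Meis1-CKO array, at least 1.46-fold lower, with log2 signals of -3.19, -3.23, -3.77 and -4.74 in control 1, control 2, Meis1-CKO 1 and Meis1-CKO 2. Since the sources used here do not say which exons were floxed, neither probe is known to lie in the deleted part, and their signals do not check the labels.

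**Figure D1:**
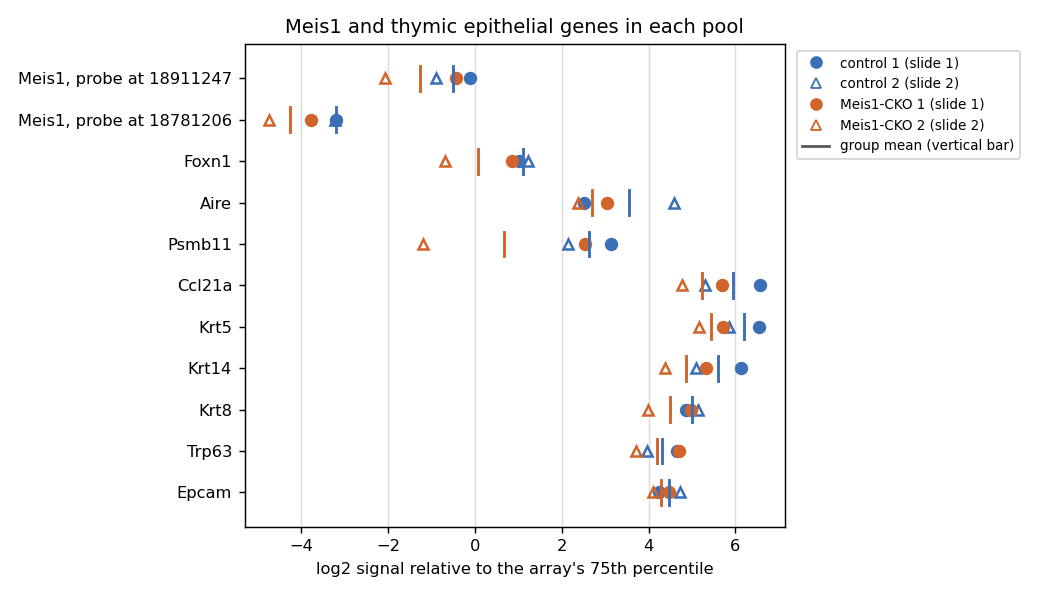
Log2 signal relative to each array's 75th percentile (horizontal axis) of both Meis1 probes, named by their mm9 start, and of 9 TEC genes in each pool. Symbols are single arrays, vertical bars group means of 2 arrays; Psmb11 in Meis1-CKO 2 lies at -1.19, below the 3 other arrays.

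Among genes above background on all 4 arrays, the differences that met the size rule were of a few log2 units. Higher in both Meis1-CKO pools than in both control pools were Sh3tc1 (log2 difference 3.02, SE 1.08), Cmbl (2.51, SE 0.59), Sh2b3, which encodes a signalling adaptor (2.38, SE 0.67), Tmbim1 (2.23, SE 0.48) and Lmo1, a LIM-only transcriptional cofactor (2.21, SE 0.78). Fut7, a fucosyltransferase (2.04), the aminopeptidase gene Anpep (2.01), Gnpda1 (2.00), Cst9 (1.95), the pyruvate dehydrogenase kinase gene Pdk4 (1.81), Ppfibp2 (1.76) and Dennd5a (1.74) followed. Lower in both were Six5, a homeobox gene (-2.71, SE 1.06), Nos2, the inducible nitric oxide synthase (-2.35, SE 0.54), Sh3rf3 (-2.18, SE 0.55), Des, the intermediate filament protein desmin of muscle (-2.16, SE 0.60), and Inka2 (-2.13, SE 0.81). The remaining ones were Maml2, a NOTCH coactivator (-2.11), the alpha-defensin genes Defa4 (-2.09) and Defa22 (-1.80), Chrac1 (-1.92), Fgf5 (-1.86), the NOTCH ligand gene Dll3 (-1.85) and Tmprss3 (-1.81).

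None of these 24 genes passed the test. At an adjusted p under 0.05, limma called 0 genes higher and 0 lower among 16810 features, and 466 features had an unadjusted p under 0.05 (227 higher and 239 lower) where chance alone would give 840.5. With the slide as a block the counts were again 0 and 0, with 662 features at an unadjusted p under 0.05. Separated arrays with at least a 2-fold difference were found for 562 features higher and 662 lower in Meis1-CKO, and 25.5% of features were separated at any size, against 33.3% by chance. The 12 named in each direction came from 40 genes higher and 69 lower that met the size rule and an unadjusted p under 0.05. The probes of some named genes disagreed in size or direction. A second Tmbim1 probe was at -0.30, a second Maml2 probe at -0.06 and a second Inka2 probe at -0.79, and the other Chrac1 probes reached -0.11.

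**Figure D2:**
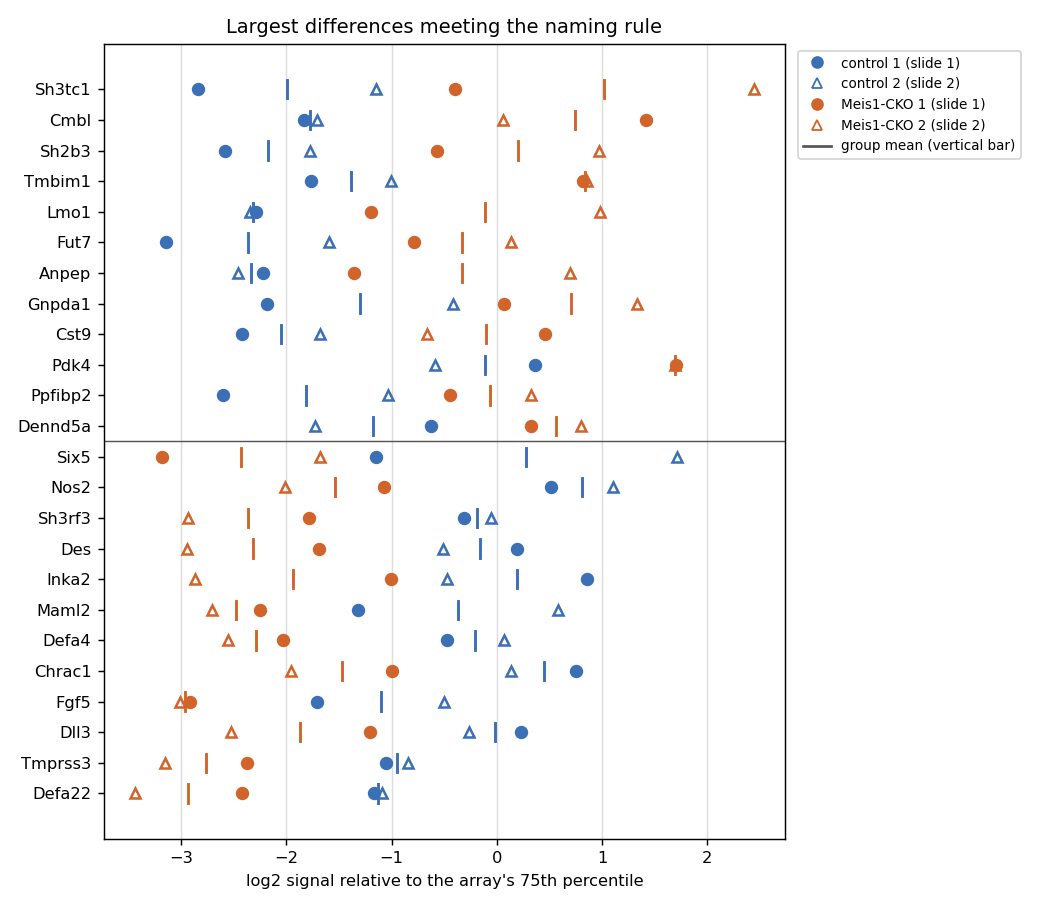
Log2 signal relative to each array's 75th percentile (horizontal axis) of the 12 genes named as higher (above the line) and the 12 named as lower (below it) in each pool. Symbols are single arrays and vertical bars group means of 2 arrays. For Nos2 the controls lie at 0.51 and 1.10 and the Meis1-CKO pools at -1.08 and -2.01.

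The 2 slides gave largely different gene differences. Sh3tc1 and Cst9 were higher on both, at 2.45 and 2.88 on slide 1 and 3.59 and 1.02 on slide 2, and Des was lower on both, at -1.88 and -2.43. Lmo1 (1.09 on slide 1 and 3.32 on slide 2) and Anpep (0.86 and 3.16) differed more on slide 2. Cmbl (3.26 and 1.76) differed more on slide 1. Across 16802 features, however, the slide 1 and slide 2 differences of Meis1-CKO minus control had a correlation of 0.01, and 46.9% had the same sign. A 2-fold difference or more was found for 2428 features on slide 1 and 4776 on slide 2. It went the same way on both for 533, where 332 would be expected if the slides were independent and all features equally likely to differ. Features that vary more can pass on both slides, and the count going opposite ways was not taken. The surplus thus does not show a shared genotype difference. Over the 14614 features above background on all 4 arrays, the slide differences had a correlation of -0.13. Without Meis1-CKO 1, limma called 200 genes higher and 117 lower in Meis1-CKO 2 than in the controls, under the assumption that the lone array varies like the others, and 0 and 0 without any other array.

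Among the TEC genes followed whatever their values, the keratin genes of medullary TECs and the chemokine gene Ccl21a read lower within both slides, while the cortical gene Psmb11 and the transcription factor gene Foxn1 were lower mainly in Meis1-CKO 2. Krt5 differed by -0.84 on slide 1 and -0.69 on slide 2, Krt14 by -0.80 and -0.71 and Ccl21a by -0.88 and -0.54. The limma log2 differences over both were -0.76 (SE 0.50), -0.76 (SE 0.60) and -0.71 (SE 0.63), each with an adjusted p of 1. Krt14 and Ccl21a were not separated, as Meis1-CKO 1 (5.33 and 5.68) read above control 2 (5.09 and 5.31), whereas Krt5 and Foxn1 were. Psmb11, which encodes the catalytic subunit of the thymus-specific proteasome, differed by -0.60 and -3.33, and by -0.10 once Meis1-CKO 2 was left out. Foxn1, needed for TEC development, differed by -0.17 and -1.90, and Aire, which drives expression of tissue-restricted antigens, by 0.53 and -2.22, with levels of 2.50 and 4.59 in control 1 and 2 and of 3.03 and 2.37 in Meis1-CKO 1 and 2. Krt8 (-0.52), Trp63 (-0.11), Epcam (-0.19), Meis2 (-0.46), H2-Aa (0.31), Cdkn1a (0.85) and Hif1a (-0.46) had overall log2 differences smaller than 1, and Cdkn1a rested on slide 2 (1.57, against 0.13 on slide 1). Without 1 array, the sign turned for Trp63 (without control 1 or Meis1-CKO 2, 0.25 and 0.39), Aire (without control 2, 0.20), Epcam (without control 2, 0.05) and Meis2 (without Meis1-CKO 2, 0.18).

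Of the gene lists, interferon response genes were higher, myeloid and dendritic cell markers were higher, and genes of muscle-like medullary TECs were lower in Meis1-CKO by camera with the preset correlation. Each of the 3 had an adjusted p = 0.93 with an estimated correlation, and so did not pass there. The 29 interferon genes tested had a median log2 difference of 0.87 (adjusted p = 2.25e-05), with Ifit2 at 2.59, Rsad2 at 1.86, Ifih1 at 1.03 and Ifit1 at 1.00. This list's median was -0.19 on slide 1, where 12 of the 29 were higher, and 1.93 on slide 2, where 28 were. The 20 myeloid and dendritic markers had a median of 0.71 (adjusted p = 0.00281), 0.10 on slide 1 and 1.23 on slide 2. The dendritic integrin gene Itgax stood at 2.95 and the complement gene C1qc at 1.49, both above background on 1 of 2 control arrays, Cybb at 0.86 and Itgam at 0.74. The 16 muscle-like genes had a median of -0.53 (adjusted p = 0.00556), 0.07 on slide 1 and -1.60 on slide 2, where all 16 were lower. Des and the muscle actin genes Actc1 and Acta1 were lower within both slides (Actc1 at -1.36 and -1.82, Acta1 at -1.18 and -1.26), whereas Myl1 was at -0.21 and -3.72.

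No list passed once the correlation was estimated, nor by fry, which tests against no change rather than against the other genes and where all 3 had an adjusted p of 0.907. With the slide as a block, camera at the preset correlation gave adjusted p-values of 2.74e-05 for the interferon, 0.000656 for the myeloid and 0.0162 for the muscle-like list. It also called 2 further lists, immediate-early genes (0.0424) and erythroid markers (0.0424). No member of any list passed over all genes tested, and 0 passed adjusted over the list alone. Without Meis1-CKO 2, the mean shifts of the interferon and myeloid lists relative to the other genes were -0.08 (adjusted p = 0.772) and -0.14 (0.763), and that of the muscle-like list was -0.18 (0.683). Without control 2 the shifts were 0.72 for the interferon list (adjusted p = 0.0676) and -0.48 for the muscle-like list (0.228), against 0.89 and -0.71 with all 4 arrays.

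**Figure D3:**
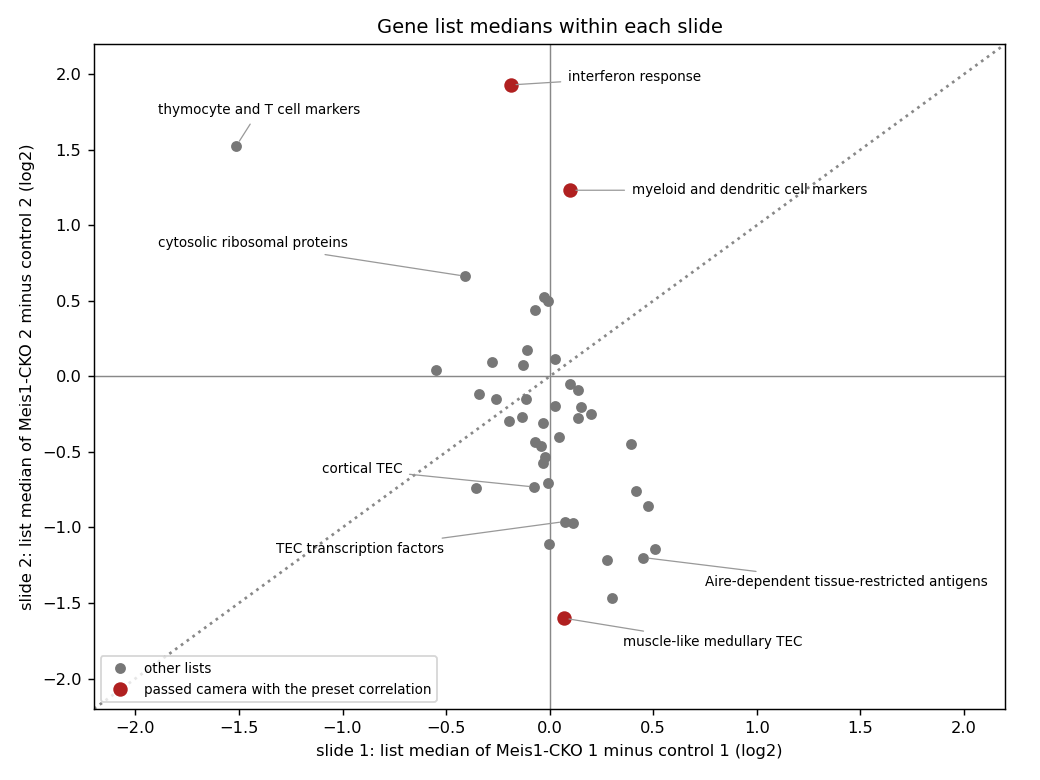
Median log2 difference of Meis1-CKO minus control of each of 43 gene lists on slide 1 (horizontal axis) against slide 2 (vertical axis). Red points are the 3 lists that passed camera with the preset correlation, grey points the other lists, and the dotted line marks equal values; the thymocyte list lies at -1.51 on slide 1 and 1.53 on slide 2.

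Markers of other cell types moved with single pools. The 24 thymocyte and T cell markers had a median log2 difference of -1.51 on slide 1 and 1.53 on slide 2, and their median level was 0.27 and -0.69 in control 1 and 2 and -1.35 and 0.83 in Meis1-CKO 1 and 2 (adjusted p = 0.862). Within this list Dntt, the terminal transferase of immature thymocytes, differed by -3.40 on slide 1 and -0.01 on slide 2, and Satb1 by 0.45 and 2.29. The signal of Arpp21 was well above background in neither Meis1-CKO pool, at least 1.84-fold lower, and Cd28, above background on 1 of 2 control arrays, had a log2 difference of 2.10. Myeloid markers had median levels of 0.79, 0.77 and 0.73 in control 1, control 2 and Meis1-CKO 1 and of 2.66 in Meis1-CKO 2, the array on which the interferon list was also highest (1.37, 0.72, 1.09 and 3.24 in the same order). Medians were -0.25 for B cell, -0.97 for erythroid, -0.03 for endothelial, -0.65 for fibroblast and -0.04 for mesenchymal genes, and -0.01 for parathyroid and thyroid markers. On slides 1 and 2 they were -0.003 and -1.11 for erythroid, 0.39 and -0.45 for endothelial and 0.30 and -1.47 for fibroblast genes. For B cell genes they were 0.14 and -0.09, for mesenchymal genes -0.20 and -0.29, and for parathyroid and thyroid markers -0.28 and 0.10. Of the sex-linked genes, Xist read 5.98, 4.32, 5.55 and 2.97 and the Y-linked Eif2s3y -1.69, 1.15, -5.77 and 2.79 in control 1, control 2, Meis1-CKO 1 and Meis1-CKO 2. Of the 5 sex-linked genes on the arrays, 2 were above background on both arrays of a group, so that list was not tested. A gene above background on 1 array of each group is left out by this rule. Eif2s3y was lowest in Meis1-CKO 1 and highest in Meis1-CKO 2, where Xist was lowest. These values point to a different mix of sexes among the pools, above all between the 2 Meis1-CKO pools. How much of the other differences comes from that mix cannot be told apart from other differences between pools or slides.

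The other TEC subset lists did not pass the test. The median log2 difference was -0.42 for the 18 cortical TEC genes, 0.07 for mature Aire-stage medullary genes, -0.12 for immature and CCL21 medullary genes and -0.44 for TEC transcription factors. Within these lists, Cd83 (0.12 and 3.63 on slides 1 and 2), Ccl17 (0.38 and 4.49) and the cathepsin gene Ctss (0.29 and 2.06) were higher mainly in Meis1-CKO 2, as was Irf8 (0.43 and 1.51). In the same array the dendritic cell gene Ccr7 (0.05 and 3.97) and the leukocyte gene Ptprc (-2.19 and 4.36), from lists added later, were also higher. Scx (-0.80 and -1.06) and Itgb4 (-0.72 and -1.13, with a further probe at 0.46) were lower within both slides, Plet1 (0.39 and 1.12) and Dll4 (0.98 and 0.54) higher. Tbx21 differed by 0.42 and -1.91. Without Meis1-CKO 2, Ccl17 differed by -0.26. Aire-dependent antigens had a median of -0.43 (adjusted p = 0.0713), with 17 of 21 genes higher on slide 1 and 0 of 21 on slide 2; Lpo stood at -1.13 and Fabp2 at -1.07, where another Fabp2 probe read 0.67. Fezf2-dependent antigens, with Maoa at 0.17 and -1.92 and Fabp7 at 0.22 and -1.77 on slides 1 and 2, had a median of -0.47 (0.28 on slide 1 and -1.22 on slide 2), keratinized medullary genes -0.20, tuft-like genes -0.25, microfold-like genes -0.20, neuroendocrine-like genes -0.60 and ciliated genes -0.27. Medians on slides 1 and 2 were 0.48 and -0.86 for keratinized, 0.51 and -1.14 for ciliated and -0.35 and -0.74 for neuroendocrine-like genes. They were -0.34 and -0.12 for tuft-like and -0.04 and -0.46 for microfold-like genes. Within the tuft-like list, the channel gene Trpm5 (-0.89 and -0.97) and the tuft lineage factor gene Pou2f3 (-0.93 and -1.52) were lower within both slides. Pou2f3 was above background on 1 of 2 Meis1-CKO arrays.

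Genes of the MEIS partner and HOX list had a median log2 difference of -0.23, with Pbx4 at 2.47 and Hoxa2 at -2.37. These values rest in part on dim signals, since Pbx4 was above background on 1 of 2 control arrays and Hoxa2 on 1 of 2 Meis1-CKO arrays. Thymocyte-attracting factors had a median of -0.44; within them the cytokine gene Tslp differed by -0.78 and -1.52, Ccl5 by -0.15 and 2.24, and Ccl19 by -0.02 and -2.22. The S phase list stood at -0.25 and the G2 and mitosis list at -0.28, with Hmmr at -0.92 (another probe at 0.44) and Cenpf at -0.85. Hypoxia and glycolysis genes had a median of -0.22, with opposite differences for Ndrg1 (1.67) and Car9 (-1.28), each going the same way on both slides. The NOTCH list had a median of -0.17, with Hes6 at -1.25 and Jag2 at -1.04, and the BMP and TGF-beta list -0.29, with Id1 at -0.77. Epithelial adhesion genes stood at -0.34, with Cldn1 at 1.78 and the integrin gene Itga3 at -0.99. Immediate-early genes had a median of 0.27 (adjusted p = 0.0617), with Klf2 at 0.94 (another probe at -0.13) and Dusp1 at 0.74.

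Medians of the other lists were 0.22 for MHC class II, 0.11 for MHC class I, -0.07 for CDK inhibitors and p53 targets, -0.29 for the unfolded protein response (Asns at -1.07), 0.05 for oxidative stress, -0.27 for WNT, -0.10 for FGF and receptor tyrosine kinase and 0.02 for NF-kappaB signalling. They were -0.11 for pluripotency factors, -0.09 for oxidative phosphorylation, -0.12 for lipid and cholesterol synthesis and 0.04 for housekeeping genes. Ribosomal protein genes had a median of 0.13, with 1 of 40 higher on slide 1 and 40 of 40 on slide 2. The 40 lists that did not pass had adjusted p-values from 0.0617 to 0.976. On the 2 slides, 27 of the 43 lists had medians of opposite sign, and 36 had the median further from 0 on slide 2.

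Alpha-defensin genes, antimicrobial peptide genes chosen after their values were seen, had the lowest p of all features. Defa-rs2 read 1.32 and 1.22 in the control pools and was well above background in neither Meis1-CKO pool. It was at least 32.7-fold lower (limma adjusted p = 0.0904), and was the 1 feature lower at an adjusted p under 0.1, with 0 higher. Its p was computed from the dim Meis1-CKO signals themselves and not from the bound. Low values had been replaced by surrogates, so the spread of such signals may not be that of the pools, and the p is uncertain. A second Defa-rs2 probe was at least 23.6-fold lower, a probe for a related cryptdin at least 10.5-fold, Defa-rs12 at least 7.12-fold and Defa1 at least 6.28-fold. In all, 13 of 15 alpha-defensin probes were lower on both slides, with a median log2 difference of -1.71, and Defa21 was at 0.00 (1.49 on slide 1 and -1.48 on slide 2). These genes are close copies of each other, so probes can bind transcripts of several of them, and single members are uncertain.

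**Figure D4:**
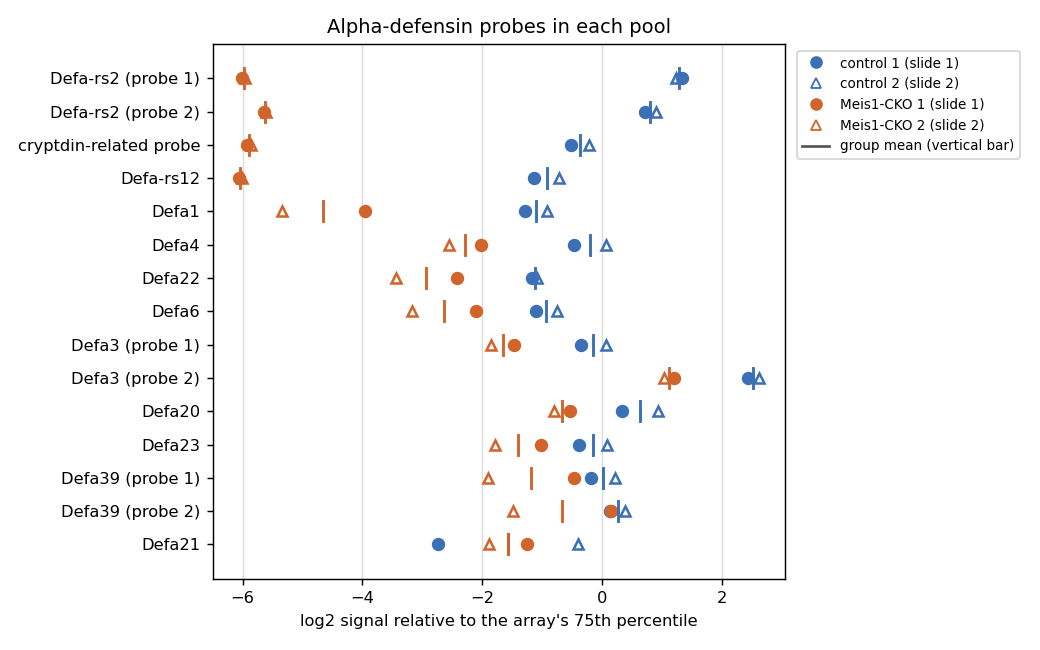
Log2 signal relative to each array's 75th percentile (horizontal axis) of 15 alpha-defensin probes in each pool. Symbols are single arrays and vertical bars group means of 2 arrays; 5 probes were well above background in neither Meis1-CKO pool.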

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

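All alternatives named here were planned. The counts of genes higher and lower stayed at 0 and 0 under every one but a threshold of 0.1, which gave 1 lower, and leaving out single arrays (0 to 200 higher and 0 to 117 lower). The high ends came without Meis1-CKO 1, a fit that sets Meis1-CKO 2 alone against the controls. The count of features at least 2-fold higher with separated arrays was 562, and 86 with normexp and quantile normalization, 870 with no filter on dim probes, 235 over features above background on all 4 arrays and 852 with all probes as separate features. The count lower was 662, and 47, 1440 and 345 in the first 3 of these settings. Quantile normalization without normexp gave 588 and 636, and the background correction and its offset were not varied apart. The filters change how many features are tested (28127 and 14635). With normexp the higher features outnumbered the lower. Leaving out single arrays gave 831 to 1994 higher and 771 to 2727 lower, since fewer arrays separate more easily.

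The Meis1 difference lay between -1.57 and 0.078 when single arrays were left out and kept its sign otherwise. Camera called 3 lists, and 6 with normexp, 4 with no filter on dim probes, 5 over features above background on all arrays, 8 with all probes, 5 with the replicate block (the slide as a block is the same fit), 2 to 17 without single arrays, and 0 with an estimated correlation or with fry. The shift of the interferon list relative to other genes was 0.89 and lay between -0.084 and 1.86 without single arrays, that of the myeloid list was 0.93 (-0.14 to 2.01), and that of the muscle-like list -0.71 (-1.25 to -0.18). An estimated correlation leaves these shifts of 0.89, 0.93 and -0.71 as they are and ends the calls by its p of 0.93. Fry, with an adjusted p of 0.907, tests a list against no change and not against the other genes. The muscle-like call was also lost with no filter on dim probes (-0.63, adjusted p = 0.183), and its adjusted p ranged from 0.000366 to 0.0162 over the other settings of signal, probes and fit that keep all arrays. The cause was not tested.

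Lists that did not pass by the planned analysis passed in some settings: Aire-dependent antigens with normexp (0.0324), features above background on all arrays (0.0264) and all probes (0.0312), immediate-early genes with normexp (0.00922), no filter (0.0121) and features above background on all arrays (0.0118), TEC transcription factors with normexp (0.0324), and erythroid markers with all probes (0.0387).

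The shift of thymocyte markers, 0.07, was -0.039 over features above background on all arrays and -0.059 with all probes. Trp63 was at 0.23 with the mean of its probes, since another of its probes read 1.11. Without single arrays the signs turned for Aire (-1.89 to 0.20), Trp63 (-0.60 to 0.39), Epcam (-0.43 to 0.050), Meis2 (-1.11 to 0.18) and Ccl17 (-0.26 to 5.13). They also turned for the thymocyte (-1.19 to 1.33), cortical (-0.78 to 0.18), mature Aire-stage (-0.18 to 0.66), immature medullary (-0.61 to 0.027), TEC transcription factor (-0.81 to 0.11), Aire-dependent (-1.01 to 0.21), erythroid (-1.52 to 0.10) and G2 and mitosis lists (-0.61 to 0.17). Of the 11 turns among those lists, 7 came without Meis1-CKO 2. Under the settings that keep all arrays, 852 values of the single genes reported kept their direction and stayed short of the threshold, and 1, that of Trp63, did not. The replicate block added immediate-early and erythroid genes to the lists called.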

Other observations

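The tests on thymocytes, myeloid genes, random lists, defensin probes without a genome position and other splits of the arrays were chosen after the results they bear on had been seen. The lists of dendritic and leukocyte genes were written after the interferon and myeloid lists. Their own genes' values had not been seen by then, apart from Ptprc, which is of the thymocyte list.

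Genes of leukocytes and dendritic cells were high in Meis1-CKO 2. Of 14 genes shared by leukocytes, 13 were higher in Meis1-CKO 2 than in control 2, with a median log2 difference of 3.13, against 2 of 14 and -0.43 on slide 1. Ptprc, which encodes CD45, read 1.44 and 1.19 in control 1 and 2, -0.75 in Meis1-CKO 1 and 5.56 in Meis1-CKO 2, although CD45-bearing cells were depleted and gated out. Of 13 genes of mature dendritic cells, 12 were higher on slide 2. Among these, the chemokine receptor gene Ccr7 differed by 3.97 and Clec10a by 3.61, against 0.05 and 0.72 on slide 1. Flt3 and Itgae were above background in neither control, but 11 of the 13 and 13 of the 14 were on both. The control pools thus held transcripts of most of these genes too, and the cells these came from were not determined. Over those 11 and 13 genes, the slide 2 medians were 1.71 and 3.12. Ptprc is also in the thymocyte list, and high leukocyte genes on slide 2 were likely once that list and the myeloid list had been seen.

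The higher interferon list of Meis1-CKO 2 may come from such cells, which needs mature dendritic genes to be higher, and their median slide 2 difference was 1.80. A high value was likely once the myeloid and dendritic list had been seen. It therefore shows dendritic transcripts in that pool, but not that they are the source of the interferon genes. A median of 1.25 for 8 myeloid lineage genes (Lyz2 at -0.49) adds nothing, as all 8 are of the myeloid list already seen. Thymocytes stay open as a source: on slide 1, where their markers were higher in control 1, the interferon list exceeded Meis1-CKO 1 by 0.19, but this is 1 other pair of arrays, and thymocyte genes such as Dntt and Satb1 differed between the slides. Noise in that pool stays open: the slide 2 median lay at percentile 100 of 10000 random lists matched on level, but random lists lack this list's estimated correlation of 0.694, and the Aire-dependent list reached percentile 100 on slide 1. A response to Meis1 loss in 1 pool alone stays open too and was not tested apart from the cells carried over. So does the mix of sexes in that pool as a source of the interferon genes, which was not tested.

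The alpha-defensin difference, seen on both slides, may reflect gene copies that the reference genome lacks, carried by the control mice and not by the Meis1-CKO mice. Loss of Paneth-like expression as a whole is argued against, because the 10 Paneth genes other than defensins had a median log2 difference of -0.28, from -0.79 to 0.37, and of 0.24 on slide 1, where 8 were higher. On slide 2 their median was -0.75 with 1 higher, so a partial loss in that pool stays open (14 intestinal epithelium genes: median -0.39, 0.29 on slide 1 and -0.86 on slide 2). All 5 probes that were not above background in Meis1-CKO had no mm9 position in the array annotation, against 0 of the 10 other probes, all on chromosome 8 (two-sided Fisher exact p = 0.000333 over probes of related genes, which are not independent). The annotation does not say why a position is missing, and no probe sequence was aligned, so absent copies were not shown. Mapped probes such as Defa4 (-2.09) and Defa22 (-1.80) were lower too, while Defa21 was at 0.00. Absent copies account for these only if such probes also bind them. A wider inherited difference stays open, as 7 of 65 genes within 5 Mb of the mapped defensin probes were separated at 2-fold, against 1203 of 16637 elsewhere (one-sided Fisher exact p = 0.189), and so does an effect of Meis1, which was not tested.

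DNA flanking the floxed allele stays open as a source of differences near Meis1. Within 10 Mb of the Meis1 probes, 3 of 71 features (4.23%) were separated at 2-fold, against 7.29% of the other features (one-sided Fisher exact p = 0.898). The controls carry 1 floxed allele, so a flanking allele with higher expression would stay under 2-fold, and this count could not show it.

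The 4 arrays allow 3 splits into pairs, too few for a share under 0.05, and all 3 splits gave at least as many separated 2-fold features as the genotypes. The genotypes gave 1224, the split by slide 2185 and the remaining split 1506, and limma called 0 features in each at an adjusted p under 0.05. Features at an unadjusted p under 0.05 numbered 466, 1139 and 551.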
